A study of Mus musculus with 8 samples.

How the data were processed

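ATAC-seq marks open chromatin through the insertion of sequencing adapters by a transposase. It was performed on leukemic granulocyte-macrophage progenitors (L-GMPs), the population that holds leukemia stem cells in the MLL-AF9 mouse model of acute myeloid leukemia, sorted from bone marrow by surface markers. Per the labels, about 5000 cells entered each reaction and libraries were amplified for 13 to 16 PCR cycles. The 8 libraries comprised 3 controls (FL), 3 Dek knockouts (KO) and 2 libraries with alanine in place of the serines at residues 306, 308, 311 and 312 of DEK (4S-A). Per the labels, FL 1 and FL 2 were Dek fl/fl and KO 1 and KO 2 carried Mx1-Cre (the Mx1-Cre set). FL 3 was Dek+/+ and KO 3 carried Tie2-Cre, and these libraries form the Tie2-Cre set with both 4S-A libraries. The series design text names only the Tie2-Cre knockout, so the Mx1-Cre genotype rests on the sample labels.

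Per the submitters' processing notes, Trim Galore 0.4.4, Bowtie2 2.2.9, Picard, MACS2 and featureCounts were used with the mm10 assembly, without the role, order or parameters of each. The authors deposited 1 narrowPeak list per library, so peaks were called per sample. The score the authors deposited for each peak was a whole number that equalled 10 times the −log10 q, truncated. The fold enrichment the authors deposited was a ratio at the summit over the local background of the same library. The authors also deposited the −log10 p and −log10 q of each peak, and the summit position. The lowest −log10 q lay between 1.30 and 1.41 in the 8 lists, close to a q of 0.05. None of these values was scaled between libraries, so they served only to rank peaks inside a list, as percentiles of −log10 q. Read depth was not stated and is unknown. List length is the only depth the lists show.

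Peaks on the 19 autosomes and X were kept. Lists were merged over all 8 libraries wherever peaks shared at least 1 bp. A union region was called lost when every control library of a comparison held a peak in it and no library of the other group did, and gained when the reverse held. Strength was the mean percentile in the libraries that held the region. Regions were assigned to the nearest protein-coding gene within 100 kb in a table of GRCm38.p6 gene spans, the assembly also called mm10. The table held 21631 protein-coding genes on these chromosomes. Because it gives neither strand nor exons, the planned promoter class became a gene end class (summit within 1 kb of either end of a gene). Exon and intron shares, sequence motifs and GC content need data that were not used here, and these planned comparisons were left out.

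Comparisons were KO against FL (3 against 3), the same contrast inside the Mx1-Cre set (2 against 2) and inside the Tie2-Cre set (1 against 1), and 4S-A against FL 3 (2 against 1). Counts of lost and gained regions were set beside those of other splits of the same libraries. Peak numbers and list coverage were compared by exact two-sided permutation tests, for which the smallest p at 3 against 3 is 0.1. List coverage was the percent of a list's union regions with a peak in a library, minus the library's percent over all union regions. The 18 gene lists covered Hox, Meis and Pbx genes, the MLL-AF9 leukemia program, hematopoietic stem and progenitor cells, granulocytes, monocytes and macrophages, erythroid cells, megakaryocytes, B cells, T and NK cells, mast cells with basophils and eosinophils, dendritic cells, endothelium and stroma, interferon response, cell cycle, apoptosis and p53, chromatin factors and DEK partners, MAPK and JAK-STAT signalling, and housekeeping. Of their 382 entries, 380 matched the table, Mx1 and Mx2 being absent from its protein-coding genes. Lost or gained labels were permuted 10000 times among regions of the same strength decile and gene end class, over the regions that could have been lost or gained. Tests were two-sided, with Benjamini-Hochberg adjustment over the lists in each direction. Where a group held 1 library no p is given. The observed number, the expected number, the 95% range of the permutations and the percentile among 10000 random lists then describe these libraries only. Overlap of losses was tested by the same permutation, and set beside 20 simulations in which each region was drawn in each library with its share of the lists of that set. Those for regions of all FL libraries were added after seeing the data. Shares carry exact Clopper-Pearson 95% intervals, and gene end shares were compared by Fisher's exact test. List similarity was the Jaccard index, the shared length over the joint length.

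Genes were named by a rule. Dek, Pbx3, Hoxa9, Meis1, Mx1, Tek and Myc were always named. For KO against FL and for 4S-A against FL, the nearest genes of the 12 strongest lost and the 12 strongest gained regions followed, with 1 region per gene and without predicted genes. Up to 4 genes per list and direction were added by the same rank. Some genes that the rule selects are not reported here. Comparisons, lists, the naming rule and the alternatives were fixed before the data were examined, except those said to have been added later.

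Alternatives were a stricter −log10 q of at least 5, windows of 250 bp on either side of the summit, 50% reciprocal overlap, all contigs, the strongest 51510 peaks of every list (equal-length lists), a strong peak criterion (within the strongest 25755 peaks of every list of the group that held it), presence in 2 of 3 libraries, 10 kb in place of 100 kb and 2 kb in place of 1 kb, random gene lists in place of permuted labels, overlap of losses without strength classes, the replicate number as a block, and leaving out each library in turn. Other controls for the 4S-A libraries, equal-length lists for gene end shares, peak numbers in the Mx1-Cre set alone and the MLL-AF9 list without Mecom were added after seeing the data. The method was tested on simulated data of the 3 against 3 comparison. Of 200 lost and 200 gained regions planted among 138385, 100.0% were recovered. This was fixed in advance, as planting followed the definition of a lost or gained region. In the same simulation, 1249 regions without a planted effect also met the criterion. Each region had the same chance in every library, so differences in set and list length were not simulated. Of 200 random lists over 44729 regions, 1.5% had a p under 0.05, and 100.0% of 100 lists with added losses did. The lists were drawn region by region, so genes whose regions change together were not covered. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.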

Results

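Open chromatin was measured by ATAC-seq in 8 libraries of L-GMPs, the progenitors that carry leukemia stem cell activity in mice with MLL-AF9 leukemia. The study asked how loss of DEK, a nuclear protein that binds chromatin, and loss of its phosphorylated serines alter chromatin in these cells. The Mx1-Cre set (set 1) held 2 controls (FL 1 and FL 2) and 2 Dek knockouts (KO 1 and KO 2). The Tie2-Cre set (set 2) held 1 control (FL 3, Dek wild type), 1 knockout (KO 3) and 2 libraries of the serine-to-alanine mutant (4S-A 1 and 4S-A 2). The labels do not say whether replicates came from separate animals.

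Lists held 51510 and 54887 peaks in FL 1 and FL 2, 56245 and 74026 in KO 1 and KO 2, 91586 in FL 3, 93041 in KO 3, and 104605 and 94725 in 4S-A 1 and 4S-A 2. List length is the only depth shown, and read depth is unknown. FL lists averaged 65994 ± 22227 peaks (SD, n = 3) and KO lists 74437 ± 18401 (SD, n = 3), a difference of 8443 that was within the spread between libraries, which includes the difference between the sets (two-sided exact permutation p = 0.5, the smallest possible being 0.1). Leaving out KO 3, which leaves FL with the only library of the Tie2-Cre set, turned the direction, with a KO minus FL difference of −858.8 peaks (two-sided exact permutation p = 1.0). Inside the Mx1-Cre set the means were 53199 for FL and 65136 for KO, and in both sets each KO list was longer than each FL list. The 4S-A lists averaged 99665 ± 6986 peaks (SD, n = 2). Lists averaged 59167 peaks in the Mx1-Cre set and 95989 in the Tie2-Cre set, so set and list length went together. The union comprised 138385 regions, of which 33321 (24.1%) held a peak in all 8 libraries. All percentiles given for a region are ranks of −log10 q within a library's own list, the strongest peak having the highest, and all intervals cover counting error only.

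**Figure D1:**
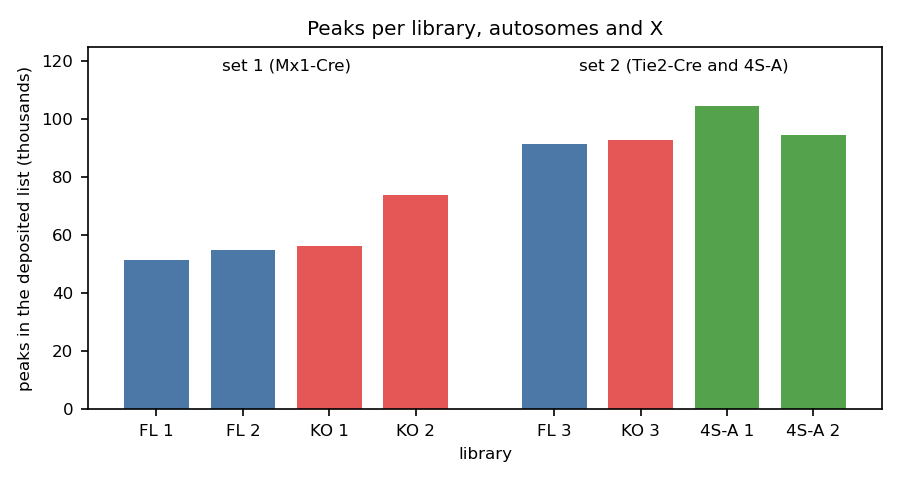
Number of peaks on the autosomes and X in each deposited list (vertical axis), with 1 bar per library, coloured by group (FL blue, KO red, 4S-A green) and separated by set. Every list of the Tie2-Cre set was longer than the longest of the Mx1-Cre set (74026 peaks).

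Dek was examined first as the targeted gene. A region inside Dek (mm10, chromosome 13, 47104867 to 47106804) held a peak in all 8 libraries, at percentiles of 65.7 and 73.1 in KO 1 and KO 2, 85.4 in KO 3, 75.6, 78.4 and 82.2 in FL 1 to FL 3, and 89.2 and 87.7 in the 4S-A libraries. A second region (47096681 to 47097135) was held only by 4S-A 1 and 4S-A 2, at percentiles of 35.0 and 33.5, and another (47099243 to 47099584) only by KO 3, at 47.3. The labels do not say which part of Dek was deleted, and a peak outside the deleted part checks nothing about the knockout.

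Pbx3, which encodes a homeodomain partner of HOX proteins, held 18 regions in its span. The strongest reached its gene end (chromosome 2, 34371079 to 34373416) and had percentiles of 94.3 to 98.8 across the 8 libraries. A second Pbx3 region in all 8 libraries (34359530 to 34360889) ranged from 88.5 to 95.9. The number of Pbx3 regions was 4, 3 and 6 in FL 1 to FL 3, 2, 2 and 15 in KO 1 to KO 3, and 9 and 7 in the 4S-A libraries. Hoxa9, a homeobox gene that MLL fusions activate, held 2 regions in all 8 libraries (chromosome 6, 52221272 to 52222341 and 52225762 to 52226575), and another (52226890 to 52227252) only in the 4 libraries of the Tie2-Cre set. Meis1, which encodes a HOXA9 cofactor, held 24 regions, 5 of them in all 8 libraries. Myc, a proto-oncogene for growth and proliferation, held a gene end region in all 8 libraries (chromosome 15, 61984808 to 61985878) at percentiles of 68.9 to 82.4.

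Mx1 and Tek were examined because their promoters drove the Cre lines. The gene end region of Mx1, an interferon-induced antiviral gene (chromosome 16, 97462591 to 97463760), stood at percentiles of 95.4 and 95.5 in KO 1 and KO 2 against 69.0 and 67.1 in FL 1 and FL 2. A shift of this size, 26.4 percentiles, was reached by 562 of 34896 regions held by all 4 libraries (1.61%). The same region stood at 70.5 in FL 3, 80.0 in KO 3 and 31.7 in 4S-A 2, and 4S-A 1 held no peak there. Per the labels, only KO 1 and KO 2 carried the Mx1-Cre transgene, whose Mx1 promoter may add reads to this region. The lists cannot tell such reads from those of the gene itself, so the shift does not show that the gene opened. Tek encodes the endothelial angiopoietin receptor TIE2. Its 4 regions were held only by both 4S-A libraries, at percentiles of at most 27.3, and by neither FL 3 nor KO 3.

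Knockout and control were compared over all 6 libraries, with a region called lost when all controls and no knockout held it and gained in the reverse case. Of 37770 regions held by all 3 FL libraries, 81 were lost, and of 45634 held by all 3 KO libraries, 344 (0.754%) were gained. The strongest lost region near a characterised gene lay 1197 bp outside Pla2g1b, which encodes a secreted phospholipase (chromosome 5, 115475712 to 115476140), at percentiles of 69.3, 42.9 and 35.4 in FL 1 to FL 3. Other lost regions were nearest to the corepressor gene Tle4, the immediate early gene Ier2, Map2k5 of the ERK5 kinase pathway, Ppp3r1 of calcineurin, the cytokine receptor gene Tnfrsf8 and the transcriptional coactivator gene Sub1. The remaining lost regions among the strongest were nearest to Thsd7b, Impact, Serpini1 and Myo16, and at the gene end of Reep2. The strongest gained region of this kind lay inside Tjp1, which encodes a scaffold of tight junctions (chromosome 7, 65410572 to 65411436), at percentiles of 73.4, 86.2 and 69.9 in KO 1 to KO 3. Other gained regions were nearest to the polarity genes Pard3 and Pard3b, the zinc finger gene Zfp64, Nup155 of the nuclear pore and the RNA-binding gene Stau1. The rest were nearest to Gltp, Slc13a3, Mtmr7, Arhgap28 and Slc36a2.

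These counts lay inside the range of the other splits of the 6 libraries, which gave 155 to 6565 lost and gained regions against 425 for knockout and control. Of the 6 splits that keep the sets balanced, 2 reached 425, the real split included, the other 5 giving 155 to 723, and in equal-length lists the real split gave 444 against 170 to 607. The split with 6565 gave 1093 in equal-length lists, where the highest was 1193. Gained regions made up 80.9% of the called regions, but in equal-length lists 193 were lost and 251 gained. No lost or gained region was among the strong peaks of every library that held it. Lost regions numbered 341, 274 and 276 without FL 1, FL 2 and FL 3, and 211 and 550 without KO 2 and KO 3. Gained regions numbered 4883 without FL 3 and 1439, 601 and 1288 without KO 1, KO 2 and KO 3.

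Gene ends were less frequent among these regions than among all regions kept. Of lost regions 11.1% (5.21 to 20.0%) lay within 1 kb of a gene end, against 27.6% of regions kept (two-sided Fisher's exact p = 0.000437) and 14.2% of kept regions of the same strength. Of gained regions 8.14% (5.48 to 11.5%) did, against 24.01% of regions kept (two-sided Fisher's exact p = 2.7e-14) and 11.1% at the same strength. The shares at the same strength lay inside both intervals. In equal-length lists 13.99% of lost regions (9.43 to 19.7%) lay at gene ends, against 11.8% at the same strength. In the same lists 3.98% of gained regions (1.93 to 7.20%) lay at gene ends, below the 11.5% of kept regions of the same strength.

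Of 18 gene lists, 0 passed the permutation test among lost regions and 0 among gained regions after Benjamini-Hochberg adjustment, with 0 and 1 at an unadjusted p under 0.05. In the list of the MLL-AF9 leukemia program, 2 regions were lost, both nearest to the transcription factor gene Mef2c, and 1 was gained, 62481 bp outside the chromatin factor gene Hmga2. In the stem and progenitor list, 2 regions were gained, near the transcription factor gene Runx1 and the stem cell marker Slamf1. In 3 further lists 1 region each was gained, nearest to the granulocyte receptor gene Csf3r, the T cell regulator Gata3 and the MAPK inhibitor Spred2. The endothelial and stromal list had 3 gained regions of 47 against 0.619 expected, nearest to Cdh5, Cxcl12 and Pecam1 (two-sided permutation p = 0.041, adjusted p = 0.738). Without replicate 1 that list had 10 gained regions against 2.99 expected (two-sided permutation test, adjusted p = 0.018), and in equal-length lists it had 0 of 31. Permuting regions treats the regions of 1 gene as separate units and measures no spread between libraries. These p values therefore describe the libraries, not the conditions. Each of the other 12 lists had 0 lost and 0 gained regions. These were Hox, Meis and Pbx genes, monocytes and macrophages, erythroid cells, megakaryocytes, B cells, mast cells with basophils and eosinophils, dendritic cells, interferon response, cell cycle, apoptosis and p53, chromatin factors and DEK partners, and housekeeping genes.

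List coverage was compared as the percent of a list's regions with a peak, minus the library's percent over all regions. Coverage of Hox, Meis and Pbx genes averaged −2.08 ± 1.49 points in FL and −10.5 ± 6.66 points in KO (SD, n = 3; two-sided exact permutation p = 0.2, the smallest possible being 0.1). The KO values were −11.6 in KO 1, −16.6 in KO 2 and −3.40 in KO 3, and the 4S-A mean was −2.98. In equal-length lists the FL mean was 3.78 and the KO mean −8.84 points (two-sided exact permutation p = 0.2, n = 3). Endothelial and stromal genes averaged −12.8 ± 3.92 points in FL, −6.45 ± 2.89 in KO (SD, n = 3; exact permutation p = 0.2) and 1.70 in 4S-A, where the mean was −4.12 in equal-length lists. Inside the sets the KO minus FL difference for the Hox, Meis and Pbx list was −11.7 points with Mx1-Cre and −2.003 with Tie2-Cre, and for the endothelial and stromal list 6.52 and 6.07. In equal-length lists the endothelial and stromal differences were 11.4 and 0.203 points. Interferon response genes averaged 9.31 ± 1.80 points in FL and 12.4 ± 2.07 in KO (exact permutation p = 0.2, n = 3), with differences of 1.64 and 5.997 points inside the sets, which were 3.52 and −3.24 in equal-length lists. None of the 18 lists passed adjustment, the smallest adjusted p from the exact permutation tests being 0.9 in the deposited lists and 0.7875 in equal-length lists.

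**Figure D2:**
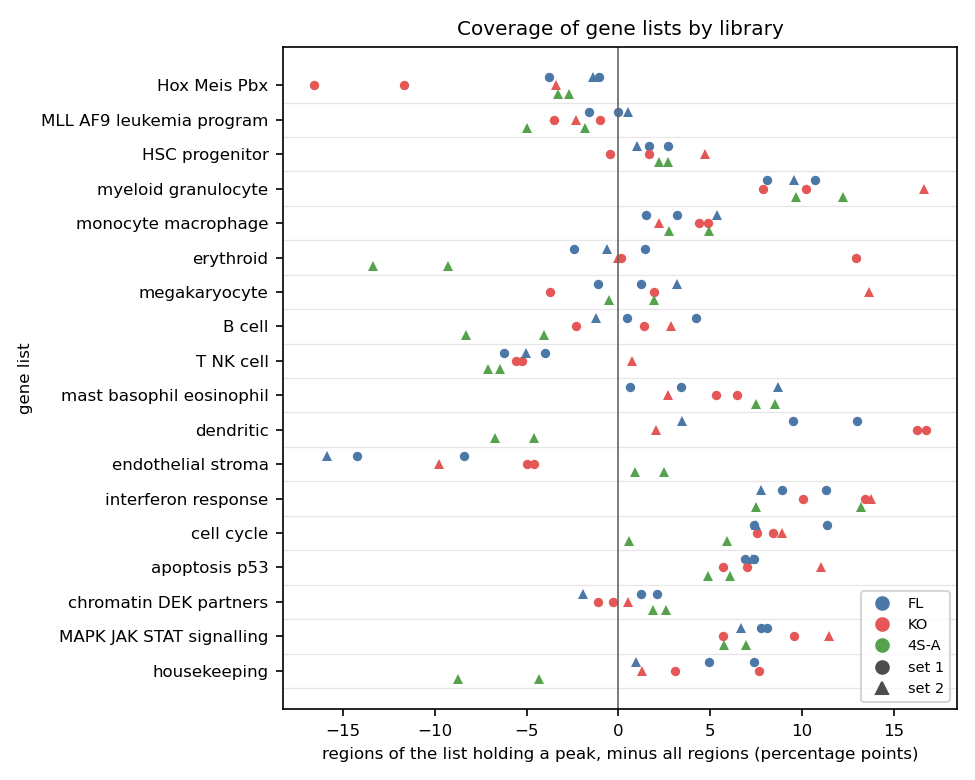
Coverage of each of the 18 gene lists in each library (percentage points above or below the library's coverage of all regions), with 1 point per library, coloured by group, as a circle for set 1 and a triangle for set 2. Hox, Meis and Pbx genes were lowest in KO 2 (−16.6 points), and endothelial and stromal genes were above 0 only in the 4S-A libraries, whose mean was −4.12 points in equal-length lists.

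Inside the Mx1-Cre set, 800 of 38582 regions were lost (2.07%) and 6495 of 48266 were gained (13.5%). The sum, 7295, was larger than the sums of the other 2 splits of these 4 libraries (2882 and 2434). Among lost regions singled out after their values were seen, the strongest lay inside Cfap58, a gene of cilia and flagella (chromosome 19, 48023648 to 48024521). It was followed by the gene end of Hoxa5, a homeobox gene of the HoxA cluster (chromosome 6, 52204079 to 52204805). The Hoxa5 region stood at percentiles of 72.3 and 79.0 in FL 1 and FL 2, 84.8 in FL 3 and 43.2 in KO 3, and no peak was held by KO 1, KO 2, 4S-A 1 or 4S-A 2. Of the 70 regions held by all 3 FL libraries and missing from those 4 libraries, it was the strongest. Its mean FL percentile was 78.7 and that of the next was 55.0. Of 12247 regions of this strength or more in all 3 FL libraries, it was therefore the only 1 missing, which follows from its being the strongest. Hoxa9, in the same cluster, kept its 2 regions in all 8 libraries. Equal-length lists gave 1911 lost and 3268 gained regions, and the strong peak criterion gave 40 and 96. Lost regions numbered 6664, 4526 and 3481 without FL 1, FL 2 and KO 2, and gained regions 10324, 20017 and 10330 without FL 2, KO 1 and KO 2. The plan gave list results of this set as values, without p, and permuted regions measure no spread between libraries here either. None of the 18 lists passed the permutation test in either direction (0 lost and 2 gained at an unadjusted p under 0.05). These 2 were endothelial and stromal genes, with 15 of 51 regions gained against 9.19 expected (two-sided permutation p = 0.0342, adjusted p = 0.308; 9 against 5.23 in equal-length lists), and MAPK and JAK-STAT genes, with 14 of 168 against 22.6 (two-sided permutation p = 0.0234, adjusted p = 0.308).

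The Tie2-Cre set compared 1 knockout with 1 control, so the difference has no replicate check. In KO 3, 12928 regions of FL 3 were missing and 13855 regions were held that FL 3 lacked. Equal-length lists gave 6619 and 6449. Of the regions gained in the Mx1-Cre set, 80.2% held a peak in FL 3 and 75.2% in KO 3, with 668 held by FL 3 alone and 344 by KO 3 alone of that pair. Of the regions lost in the Mx1-Cre set, 81 were held by FL 3 alone and 55 by KO 3 alone, and 193 and 201 in equal-length lists. The MLL-AF9 program had 115 of 516 regions missing in KO 3 against 87.8 expected (95% permutation range 73 to 102, as a description of these libraries). Without Mecom the same list had 80 against 79.3. Stem and progenitor genes had 27 missing regions against 44.1 (34 to 55), and granulocyte genes had 7 against 16.0 (10 to 23). Also below their range were megakaryocyte genes with 3 against 8.69, T and NK cell genes with 7 against 13.3, apoptosis and p53 genes with 13 against 20.7, and MAPK and JAK-STAT genes with 24 against 33.5. Of these 6 lists, granulocyte genes and MAPK and JAK-STAT genes stayed below in equal-length lists, with 3 against 11.7 and 15 against 23.3. Endothelial and stromal genes had 29 of 99 regions gained against 20.9 (14 to 28), but 9 against 7.55 (3 to 12) in equal-length lists, and 29 lay inside the range of random gene lists (10 to 29).

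The mutant comparison asked what changes in chromatin accompany loss of the 4 serines. Of 89572 regions in FL 3, 10517 (11.7%) were missing from both 4S-A libraries, and of 84377 regions in both 4S-A libraries, 13819 (16.4%) were missing from FL 3. With KO 3 in the place of FL 3 the counts were 9878 and 12645. FL 3 was the only control of the set, so the difference has no replicate check on the control side. The strongest region lost near a characterised gene lay at the gene end of H13, which encodes signal peptide peptidase (chromosome 2, 152686717 to 152687287, percentile 93.0), and was held by FL 3 alone. The others included Rasa2, which encodes a Ras GTPase activator (chromosome 9, 96544046 to 96544574, percentile 90.0), the neurexin family gene Cntnap2 (chromosome 6, 45271440 to 45272038, 89.9) and Mecom, which encodes the stem cell transcription factor EVI1 (chromosome 3, 30091727 to 30092725, 86.3). The gene end of Hoxa5 was also among them, as were the retinoic acid receptor gene Rarb, the gene end of Hmgn3, which encodes a nucleosome-binding protein, and the fatty acid receptor gene Cd36. The list was completed by Snd1, Vwa5a, Dab1 and Pex3. Of these 12 regions, 7 held a peak in all 6 FL and KO libraries and 9 in KO 3.

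The strongest region gained near a characterised gene in the 4S-A libraries lay at the gene end of Cyp2r1, a vitamin D hydroxylase gene (chromosome 7, 114562443 to 114563305), at percentiles of 97.6 and 95.6. Others lay near Ppp1r14c, an inhibitor of protein phosphatase 1 (chromosome 10, 3336697 to 3337366), and the carboxylesterase gene Ces1f. Guidance receptor and ligand genes followed with Plxna4, Sema6a and Ephb1, and the retinol receptor gene Stra6, the protease inhibitor gene Serpina10 and the cytokine gene Il10. Olfr1254, Rnf165 and Hydin completed the 12, of which 8 were held by no FL or KO library. In equal-length lists 7084 regions were lost and 6361 gained. The strong peak criterion gave 31 lost and 296 gained regions. Without 4S-A 1 there were 16814 lost regions, and without 4S-A 2 there were 24663 gained regions. Of lost regions 5.77% and of gained regions 5.35% lay at gene ends, against 7.94% and 8.64% of kept regions of the same strength.

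Gene lists placed these regions by function. The MLL-AF9 program had 96 of 516 regions lost in the 4S-A libraries against 71.4 expected (58 to 85), at percentile 99.985 of random lists as a description of these libraries. Without Mecom the list had 65 against 64.5, without 4S-A 1 its ratio to expectation was 1.07, and in equal-length lists it had 42 against 41.4. Its other lost regions included the kinase gene Cdk6, the RNA-binding gene Igf2bp3 and the surface marker Cd47. Hox, Meis and Pbx genes had 13 lost regions against 12.3 (7 to 18), led by Hoxa5, Pbx3 (chromosome 2, 34139843 to 34140178, percentile 41.3 in FL 3) and Meis1, and 13 gained regions against 13.4 (8 to 19). Endothelial and stromal genes had 40 of 113 regions gained against 25.4 (18 to 33), at percentile 98.8 of random lists, and 12 against 8.19 (4 to 13) in equal-length lists. The gained regions were nearest to 11 of 13 genes of that list, led by Lepr, Cdh5, Pdgfrb and Kdr. Below their range were gained regions of dendritic genes with 5 against 12.1 (7 to 18), cell cycle genes with 18 against 28.5 (20 to 37) and stem and progenitor genes with 41 against 53.5 (42 to 65). Against random gene lists and without 4S-A 2, 0 of the 18 lists lay below. In equal-length lists 5 lay below, within 10 kb 3 did, and without 4S-A 1 there were 2. Monocyte and macrophage genes had 35 gained regions against 31.2 (22 to 40), the strongest near Irf8 and F13a1, which encode a monocyte transcription factor and a coagulation factor subunit.

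Mecom carried most of the excess in the MLL-AF9 program, and its locus was examined after the values were seen. Its span (chromosome 3, 29951296 to 30509759) held 43 regions, of which FL 3 held 40, KO 3 6, FL 1 and FL 2 5 and 7, KO 1 and KO 2 13 and 12, and the 4S-A libraries 12 and 11. Of the 40 regions of FL 3, 30 (75%) were missing from both 4S-A libraries against 6.73 expected, and 34 (85%) were missing from KO 3. In the flanking 1 Mb on both sides, 10 of 81 FL 3 regions (12.3%, 6.08 to 21.5%) were missing from the 4S-A libraries. The lower flank held 1 region of FL 3, so that share describes the upper flank.

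**Figure D3:**
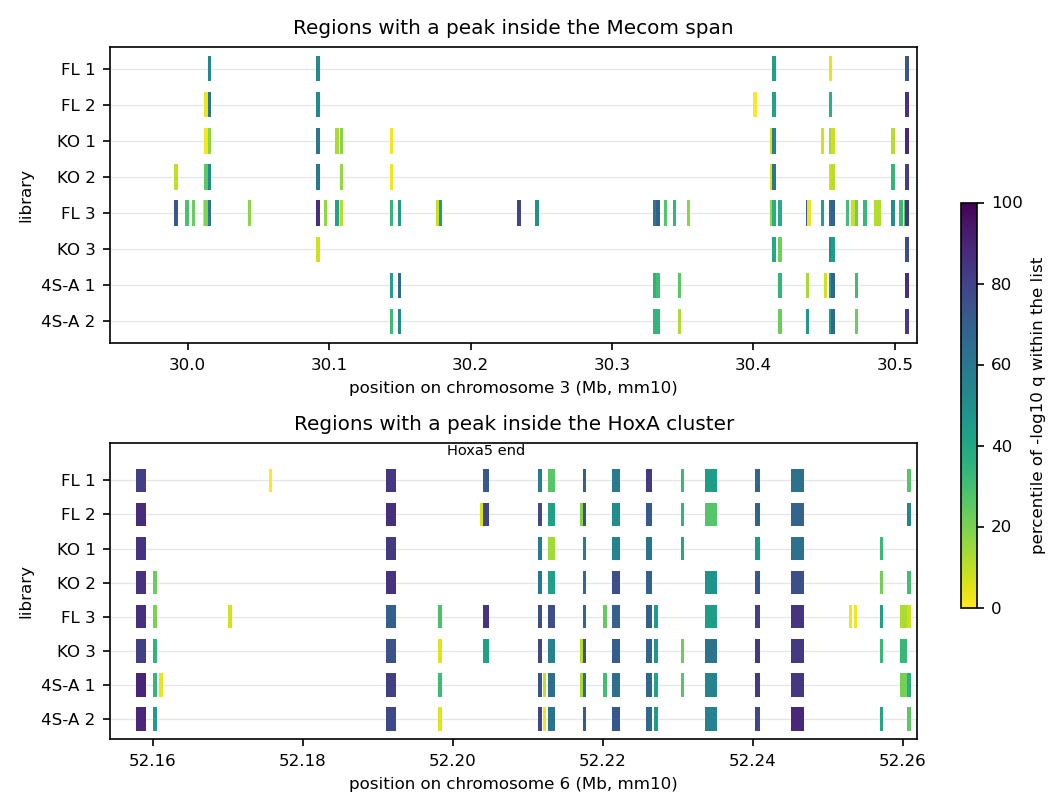
Regions with a peak in each of the 8 libraries across Mecom (chromosome 3) and the HoxA cluster (chromosome 6), with position on the horizontal axis (mm10) 1 line per library and colour for the percentile of −log10 q within the list; narrow regions are drawn wider than they are so that they can be seen. FL 3 held 40 of the 43 Mecom regions and KO 3 held 6, and 9 of the 27 HoxA regions were held by all 8 libraries.

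Losses in knockout and mutant were then compared among regions held by every control. Of 37770 regions held by all 3 FL libraries, 550 were missing from KO 1 and KO 2 and 853 from both 4S-A libraries. Both losses met in 70 regions against 46.2 expected (34 to 58; two-sided permutation p = 0.0006), among them the gene end of Hoxa5. Because both losses were counted in regions of the same 3 FL libraries, unchanged libraries were simulated. Their losses met 4.78 times as often as in independent lists (54.3 regions), against 5.64 times observed, where independent lists would share 12.4. The simulated losses numbered 1313.3 and 365, against 550 and 853 observed, so the 2 ratios are not like for like. In equal-length lists the observed losses met in 186 regions against 169.6 (two-sided permutation p = 0.134). Loss in KO 1 and KO 2 and loss in KO 3 met in 81 regions against 32.0 (22 to 42), and in 193 against 142.8 in equal-length lists. By definition these are the regions already counted as lost at 3 against 3, so this overlap is no separate result. The 81 regions were 11.1 times the number for independent lists (7.27), against 4.69 times in unchanged libraries simulated in the same way (117.5 regions). Those simulated losses numbered 1313.3 and 805.3, against 550 and 499 observed, so these ratios are not like for like either. Part of each excess may come from the shared controls. These permutations of regions describe the libraries, not the conditions.

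With FL 3 as a shared control, 6563 regions were missing from KO 3 and from both 4S-A libraries, 50.8% of the 12928 missing from KO 3. Independent lists would share 1518, the observed number being 4.32 times that, and permutation within strength classes gave 3862. Unchanged libraries simulated against the same control shared 3940 regions, 4.70 times the number for independent lists, so the shared control alone gave an excess of this kind. The simulated losses numbered 12017.4 in KO 3 and 6494.85 in 4S-A, against 12928 and 10517 observed, so these ratios are not like for like. The shared regions were 32.8% of the simulated KO 3 losses, below the 50.8% observed. With KO 3 as the control the shared regions were 5924, or 3.92 times. A single control library cannot be split, so part or all of the excess may come from it.

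Libraries resembled their set more than their genotype. The mean Jaccard index was 0.647 for pairs of the same set and group and 0.610 for pairs of the same set and different groups. It was 0.408 for the same group across sets and 0.388 for different groups across sets. Equal-length lists gave the same order, with 0.682, 0.638, 0.459 and 0.442. Of the 28 pairs of libraries, the 4S-A pair had the most regions of its own, with 8230 held by it alone and 467 missed by it alone, 8697 in all. The next pair, FL 1 and FL 2, had 3989.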

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

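All tests of explanations in this part were chosen after the results were seen. Several values differed between FL and KO one way in the Mx1-Cre set and the other way in the Tie2-Cre set, and the difference was not tested. The KO minus FL difference in median peak width was 16 bp with Mx1-Cre and −38 bp with Tie2-Cre. The difference in covered length was 6.23 Mb and −0.896 Mb, and that in median fold enrichment was 0.398 and −0.101. Coverage differed by 2.31 and −3.16 points for monocyte and macrophage genes such as Spi1 and Csf1r, by 3.87 and −5.99 points for mast cell, basophil and eosinophil genes such as Gata2 and Mitf, and by 5.27 and −1.43 points for dendritic cell genes such as Zbtb46 and Cd74. Chromatin factors and DEK partners differed by −2.36 and 2.43 points. In equal-length lists the 2 sets still differed in sign for monocyte and macrophage genes (4.09 and −2.67 points). They had the same sign for mast cell, basophil and eosinophil genes (2.37 and 8.82), dendritic cell genes (4.80 and 3.73) and chromatin factors and DEK partners (−1.77 and −3.93). These rest on 4 libraries in the first set and 2 in the second.

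Regions gained with Mx1-Cre were held less often by KO 3 than by FL 3. Unequal list length does not account for it, because KO 3 had the longer list (93041 peaks against 91586). In equal-length lists KO 3 still held fewer of them, by −4.74 percentage points. These lists do not equalise peak width, whose median was 436 bp in FL 3 and 398 bp in KO 3. A general lean of FL 3 over KO 3 stays open. In the deposited lists FL 3 alone stood to KO 3 alone at 1.94 for gained and 2.02 for other regions (odds ratio 0.963). In equal-length lists other regions leaned more to FL 3, with 1.62 and 2.03 (odds ratio 0.797). Regions lost with Mx1-Cre leaned less to FL 3 than other regions, with odds ratios of 0.455 in equal-length lists and 0.757 in the deposited lists. These ratios compare 1 library with 1 library, so whether the lean differs between kinds of region cannot be tested. The set, the Cre line and the sex of the cells cannot be told apart, since pairs of the same group across sets had a Jaccard index of 0.408 against 0.610 for different groups inside a set, and a different response to DEK loss in the 2 models may add to this and was not tested.

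The 4S-A libraries stood apart from the other 6. List length does not account for this, because in equal-length lists 4358 regions were held or missed by this pair alone against at most 1673 for any other pair. Chance stays open, since 1 of the 12 pairs inside a set reached 8697 regions, the next had 3989, and 12 pairs are too few for a share under 0.05. X chromosome dosage could add few regions at most, as 2.76% of gained regions were on X against 2.03% of kept regions. Endothelial or stromal cells in the sort are a candidate source that stays open. Gained regions at their genes stood at 1.46 times expectation in equal-length lists and 1.57 in the deposited lists, with Cdh5 and Kdr among the genes in both. The excess is not particular to 4S-A, as the Mx1-Cre knockouts had 1.72 and 1.63. The sort selects Kit-positive cells without lineage markers, and whether it excludes such cells was not tested. A response to the serine changes may produce the same values and has no separate test here.

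Mecom held many more regions in FL 3 than in the other 7 libraries. Weak peaks do not account for it, since 30 regions were missing from the 4S-A libraries against 6.73 expected from their strength. A copy number or mapping change over a wider segment is argued against by the flanks, where 12.3% of FL 3 regions were missing against 75% inside Mecom, although the lower flank held 1 such region. In the Mx1-Cre set, KO libraries held 12.5 Mecom regions on average and FL libraries 6, the reverse of a loss with altered Dek. The controls FL 1 and FL 2 held only 5 and 7, so a loss of the FL 3 regions could hardly appear there. Altered Dek as the cause therefore stays open. A property of the single library FL 3, such as its leukemia clone, may remain, and no value here decides it.

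The 6 libraries of the 3 against 3 comparison form 10 splits, too few for a share under 0.05. The real split gave 425 lost and gained regions, 6 of the 10 splits gave as many, and the highest other gave 6565. That split, FL 1, FL 2 and KO 1 against FL 3, KO 2 and KO 3, gave many times the real count, which points to a structure of the samples along the sets and list lengths. In equal-length lists it gave 1093 against 444 for the real split, and the highest was 1193. Of the 6 splits that keep the sets balanced, 2 reached 425, the real split included (the others gave 155 to 723). Inside the Mx1-Cre set the count was 7295.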

How the results depend on the processing

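The MLL-AF9 list without Mecom, FL 3 with KO 3 or all 6 FL and KO libraries as controls for 4S-A, equal-length lists for gene end shares and peak numbers in the Mx1-Cre set alone were tried after seeing the data, and the other alternatives were planned. Of 204 alternative values, 139 were counted as kept, 55 moved, 7 became weaker, 1 became stronger and 2 reversed. Kept values held their direction and side of the threshold or stayed within 1.5 times. The 18 coverage differences in equal-length lists were counted as kept without a check, as no list passed. Of these 18, 2 changed sign, those of B cell genes and of MAPK and JAK-STAT genes. The stricter q threshold, summit windows and all contigs kept every count of lost and gained regions within 1.5 times. List similarity kept its order. Gene end shares stayed below those of all regions kept, although at 3 against 3 the lost share was 21.0% within 2 kb and 13.99% in equal-length lists, both above the 20.2% and 11.8% at the same strength, and the gained share was 13.1% and 3.98%. The motif alternatives were not run.

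In equal-length lists, 193 regions were lost in the 3 against 3 comparison, 1911 were lost and 3268 gained with Mx1-Cre, 6619 were lost and 6449 gained with Tie2-Cre, and 6361 were gained in 4S-A. The strong peak criterion left 0 lost and 0 gained regions at 3 against 3, and 40 and 96 with Mx1-Cre. It left 43 and 18 with Tie2-Cre, and 31 and 296 in 4S-A. This criterion admits fewer regions, and most called regions were weak. Above median strength were 1 of 81 lost and 8 of 344 gained regions at 3 against 3. With Mx1-Cre 68 of 800 and 546 of 6495 were, and with Tie2-Cre 343 of 12928 and 353 of 13855. In 4S-A 391 of 10517 lost and 2319 of 13819 gained regions were. Reciprocal overlap, which splits more regions by construction, gave 142 lost and 970 gained at 3 against 3, 2084 lost with Mx1-Cre, 19541 lost and 20996 gained with Tie2-Cre, and 15776 lost in 4S-A. Presence in 2 of 3 libraries gave 729 lost and 2640 gained. With all 3 FL libraries as the control for 4S-A, 853 regions were lost. With FL 3 and KO 3 together 3954 were lost and 9140 gained, and with all 6 FL and KO libraries 467 and 8230, as more libraries must then be unanimous.

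Leaving out libraries loosens unanimity. It gave 87 to 550 lost and 417 to 4883 gained regions at 3 against 3, 1005 to 6664 and 9541 to 20017 with Mx1-Cre, and 12717 to 16814 and 18495 to 24663 in 4S-A. The p for peak number ranged from 0.2 to 1.0 (two-sided exact permutation tests), and without KO 3 the difference reversed to −858.8 peaks (p = 1.0), since FL 3 was then the only library of the Tie2-Cre set. Lists past the threshold ranged from 0 to 1 among gained regions at 3 against 3, and those outside the range from 1 to 2 among lost and 1 to 3 among gained regions of 4S-A.

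Lists outside their range among regions lost with Tie2-Cre numbered 7, and 4 within 10 kb, 3 in equal-length lists and 4 against random gene lists. Among regions lost in 4S-A there was 1, and 3 within 10 kb, 0 in equal-length lists, 3 against random gene lists and 0 without Mecom. Among regions gained in 4S-A there were 4, and 4 within 10 kb, 5 in equal-length lists and 1 against random gene lists. The cause was not tested. The endothelial and stromal ratio for gained regions at 3 against 3 reversed from 4.85 to 0 in equal-length lists, with 0 of 31 regions. Overlap of the losses in the Mx1-Cre knockouts and 4S-A fell to 1.10 times expectation in equal-length lists (two-sided permutation p = 0.134), and the cause was not tested.

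With the replicate number as a block, the p for peak number was 0.25 (exact sign-flip test, n = 3, the smallest possible), and the smallest p for list coverage was 0.25, a test too small to pass the threshold either way. Same-numbered libraries correlated at 0.172, 0.0857 and 0.327, and FL 2 correlated best with KO 1 (0.185), so not every library matched its own number. The peak names inside the lists labelled KO 1 and KO 2 carry the numbers 2 and 3, by which FL 2 would meet KO 1, so what the block and these correlations pair is uncertain. Depth limits the comparisons between sets, because list length separates them.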

Other observations

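The genes in this part were singled out after their values were seen, as were the tests on them. Some genes gained or lost most of their regions in the 4S-A libraries. They were picked from the top of scans over 5716 genes for gains and 6184 for losses. For the Mx1-Cre set the scans covered 2914 and 2083 genes. An excess over expectation follows from this choice. Ncald, which encodes the calcium sensor neurocalcin delta, had 17 of 22 regions gained against 3.51 expected. The teneurin gene Tenm4 had 28 of 37 gained, the galactosyltransferase gene B3galt1 had 14 of 14, and the collagen genes Col25a1 and Col6a3 had 19 of 26 and 16 of 19. Clnk, which encodes an adaptor of immunoreceptor signalling, lost 13 of 13 regions against 2.29 expected, and the semaphorin gene Sema6d lost 11 of 15. In the Mx1-Cre set, Ncald gained 6 of 8 regions and the receptor gene Ror1 7 of 8, while Cfap58 lost 5 of 6.

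Sex-linked genes separated the libraries. Of the Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y, 0 of 4 held a peak in the libraries of the Mx1-Cre set and 4 of 4 did in those of the Tie2-Cre set. Xist held 4 regions, which did not divide the libraries in 1 way. The first (chromosome X, 103477544 to 103478027) held a peak in all 8 libraries. The next (103481390 to 103482176) held peaks in the Mx1-Cre set at percentiles of 70.02 to 77.95 and in 4S-A 1 and 4S-A 2 at 63.5 and 58.0, and in neither FL 3 nor KO 3. The region at the gene end (103483134 to 103483368) was held by FL 1, FL 2 and KO 2 alone, and the last (103484119 to 103484318) by 4S-A 2 alone. No test of cells from a second source was run.

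Gene ends of endothelial and stromal genes held 7 peaks in FL 3, 10 in KO 3, and 12 and 11 in the 4S-A libraries, of 15 such regions. Of these, 3 were held in the Tie2-Cre set only by both 4S-A libraries, at Tek and Cdh5.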
